A study of Mus musculus with 5 samples.

How the data were processed

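RNA from 5 samples of sorted mouse tracheal epithelial cells was hybridised to an Affymetrix mouse genome-wide 3' expression array, per the labels: 2 samples of basal cells and 3 of duct cells, each from its own pool of mice. The deposited table gives 1 linear intensity per probe set and array. Its values show that the authors scaled each array: the mean intensity after dropping the lowest and highest 2% of probe sets is 500.0 on all 5 arrays. The sorted values differ between arrays, so the deposited intensities were not quantile normalized. The probe set summary method, the background correction, the software and any detection calls are not given in the sources used here. No column of another sample was present (0).

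The table holds 45101 probe sets, of which 64 are control probe sets and were left out of the tests. Probe sets were named from the platform's gene annotation: 34945 had 1 gene symbol, 932 had several and 9160 had no listed gene. Symbols were checked through Entrez identifiers against the mouse reference gene table of assembly GRCm38.p6, and 0 needed updating; no coordinates were used. Probe sets with several genes or no listed gene name no gene and were tested only in the count by probe set. The most intense probe set, by mean over the 5 arrays, stood for each of 18193 genes. Probe sets in the lowest 40% by mean were left out before the adjustment, which left 12536 genes. Where a named gene had several tested probe sets, their fold changes were compared: those of Dcn, Egfl7, Itgav, Mbp, Nfkbia, Sox5, Tpm1 and Xist differed in sign.

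Fold changes are duct minus basal on the log2(intensity + 16) scale, which understates the change of dim genes, with no further normalization. They were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0), 2-sided, on all 5 arrays without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 3 residual and 2.79 prior degrees of freedom. Means and SDs are of linear intensities in arbitrary units. With no detection calls, 27 probe sets for Bacillus transcripts, at 0.561 to 86.5, served as a measure of background. Where every array of the lower group was at or below its brightest such probe set, the fold is given as at least the ratio to that level, from means of log2 values. All adjusted p-values of genes are limma's.

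Before the data were examined, 36 gene lists were fixed from textbook knowledge; 32 were tested with camera (limma) at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, each adjusted over the lists. Lists of sort antigens and of sex-linked genes were not tested, and 2 had too few tested members. Also fixed then were the design, the alternatives and the genes to name. These are the sort antigens, of which only Itga6 is reported here; Krt5, Krt14, Krt15, Krt17, Trp63 and Ngfr; the 10 largest increases and 10 largest decreases past the threshold whose groups did not overlap, leaving out clone and RIKEN names (predicted-gene names were treated alike); up to 4 called members, by size, of each list that passed camera or had 3 or more members called; and up to 2 members with the highest mean level of each described list with none called. Genes named outside this rule are said to have been chosen after their values were seen.

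The replicate numbers in the labels do not pair samples, which came from separate pools. No pair of arrays shared more than 1 identical value, so all were kept as separate replicates. Alternatives were quantile normalization, centring on array medians, pseudocounts of 1 and 64, no filter and a filter at 60%, the mean of a gene's probe sets, exclusion of possibly cross-hybridising probe sets, an intensity trend with robust fit, array weights, the replicate number as a block, each array left out in turn, probe sets as the unit, and a 2-fold minimum. With 1 basal array left, that array is assumed to vary like the duct arrays. The mean of a gene's probe sets also took in probe sets that the main filter left out as dim.

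The fit was tested on simulated data for 12536 genes with the group sizes of duct against basal, in 20 draws with 200 changed genes each. It called 1.99% of genes changed by 1 on the log2 scale, 59.8% of those changed by 2 and 97.7% of those changed by 4, and 6.24% of calls were false. With nothing changed, camera at the preset correlation called 1 of 640 list tests. Genes were drawn independently of each other, so the draws cannot test the preset where a list's genes vary together. In the data the estimated correlation was 0.334 for the squamous, 0.181 for the cell cycle, 0.179 for the thyroid and 0.0823 for the interferon list. With the interferon list lowered by 1, it was called in 20 of 20 draws, and in 0 with an estimated correlation. Figures were drawn with matplotlib 3.10.9.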

Results

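Gene expression was measured by array in epithelial cells sorted from the tracheas of C57BL/6 mice, described as being of both sexes. The basal group held 2 arrays, from surface epithelium freed with the enzyme dispase and sorted by surface antigens that included ITGA6. The duct group held 3 arrays, from the ducts of the submucosal glands: surface epithelium was removed with the enzyme pronase and cells were sorted by a surface antigen, without ITGA6, from the tissue that remained. Basal cells came from the lower part of the trachea and duct cells from the upper part, so enzyme, section and sort gate changed together with the cell type. Each of the 5 samples was a separate pool of mice. The share of probe sets above the brightest Bacillus control probe set, used here as a measure of background, was 71.6% and 62.5% on the basal arrays and 67.2%, 74.6% and 72.5% on the duct arrays. The small number of arrays limits the precision.

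The arrays of a group lay together. Over the 12536 tested genes, Pearson correlations across genes were 0.924 between the basal arrays, 0.911 to 0.935 among the duct arrays and 0.848 to 0.896 between groups; genes are not independent replicates. The first principal component, with 48.7% of the variance, placed the basal arrays at -59.2 and -45.1 and the duct arrays at 55.0, 16.3 and 32.9. The second, with 24.0%, separated duct replicate 1, at 48.0, from duct replicates 2 and 3, at -20.1 and -44.9. Duct replicate 1 also had a median intensity of 92.3, against 146.5 to 152.8 on the other 4 arrays. The Y-linked gene Eif2s3y, chosen after its values were seen, measured 163.6 and 532.1 on the basal arrays and 787.8 and 693.9 on duct replicates 1 and 2. On duct replicate 3 it measured 3.06, under that array's brightest Bacillus control probe set, at 61.9.

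The comparison of duct with basal cells asks how these airway populations differ in gene expression. Of 25 tested genes of stratified squamous epithelium 14 rose in duct cells and 0 fell (camera adjusted p = 3.65e-23; adjusted p = 0.405 with an estimated correlation). Krtdap, a secreted protein of differentiating keratinocytes, rose from 45.7 ± 3.04 (SD, n = 2) to 13993 ± 2682 (SD, n = 3), and Lgals7, a galectin of stratified epithelia, from 39.5 ± 8.54 to 3802 ± 635. Krt14, a keratin of basal cells of stratified epithelia, rose 13.7-fold, while Krt5, Krt15 and Trp63, which also mark basal cells, did not pass the test. Tg, the thyroglobulin gene, had the largest log2 fold change as measured, from 32.2 ± 29.8 to 14987 ± 5746. Duct cells had lower levels of Bmp5, a bone morphogenetic protein ligand, of Porcn, the acyltransferase that Wnt secretion needs and of Lgr6, a receptor for R-spondins.

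Of the 12536 genes, 122 differed at an adjusted p under 0.05 with limma, 105 higher and 17 lower in duct cells. All 122 differed by at least 2-fold on the log2(intensity + 16) scale, and in all 122 the duct and basal arrays did not overlap. Over all tested genes 4904, or 39.1%, did not overlap, against 20% by chance for 2 against 3 arrays. At an unadjusted p under 0.05, 991 genes were higher and 1332 lower. The median fold change of all tested genes was -0.12; it was -0.05 with quantile normalization and 0.08 with each array centred on its median, so small fold changes are read against these values. For 31 of the genes that were higher, both basal arrays were within the range of the Bacillus controls, and where such a gene is named below its fold is also given as a lower bound.

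The calls rested on all 5 arrays. Without basal replicate 2, limma called 0 genes (927 higher and 889 lower at an unadjusted p under 0.05); without basal replicate 1 it called 2 higher and 0 lower, and without duct replicates 1, 2 and 3 it called 38, 23 and 1 higher and 1, 0 and 0 lower. In every fit in which it was tested, each of the 23 called genes picked by the naming rule kept its direction; Zfp810 was not tested without either basal array or with the lowest 60% of probe sets left out.

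The 10 largest increases were led by Tg, at a log2 fold change of 8.35 (SE 0.54, adjusted p = 0.00595) and at least 161-fold. Krtdap followed at 7.81 (SE 0.26, adjusted p = 0.00192) and at least 157-fold. Lipf, a gastric lipase gene, was at 7.01 and at least 52.3-fold, with 22.5 ± 20.3 in basal and 4599 ± 361 in duct cells. Mt4, a metallothionein of stratified epithelia, was at 6.74, from 84.3 ± 23.6 to 11007 ± 3696. Lgals7 was at 6.10 and at least 42.9-fold. Sprr1b, a small proline-rich component of the cornified envelope, was at 5.89 and at least 24.7-fold. Chit1, a chitinase gene, was at 5.70 and at least 24.4-fold. Tgm3, an epidermal transglutaminase, was at 5.68, Crct1 at 5.68 and at least 45.5-fold, and Dmkn, the gene of dermokine, at 5.47. The order is that of the fitted log2 fold change, and the lower bounds do not settle it. They do not rank Tg against Krtdap, and Lipf stands before Mt4, which was 107-fold higher as measured. Mt4 and Tgm3 have no lower bound because basal replicate 1 lay above its controls. On basal replicate 2 they measured 67.7 and 77.1, under that array's brightest Bacillus control, 86.5. The adjusted p of these 10 genes ran up to 0.0105, the value of Sprr1b. Gm94 had a log2 fold change of 6.49, at least 73.1-fold, but carries a predicted-gene name that the naming rule leaves out; it is given after its value was seen.

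**Figure D1:**
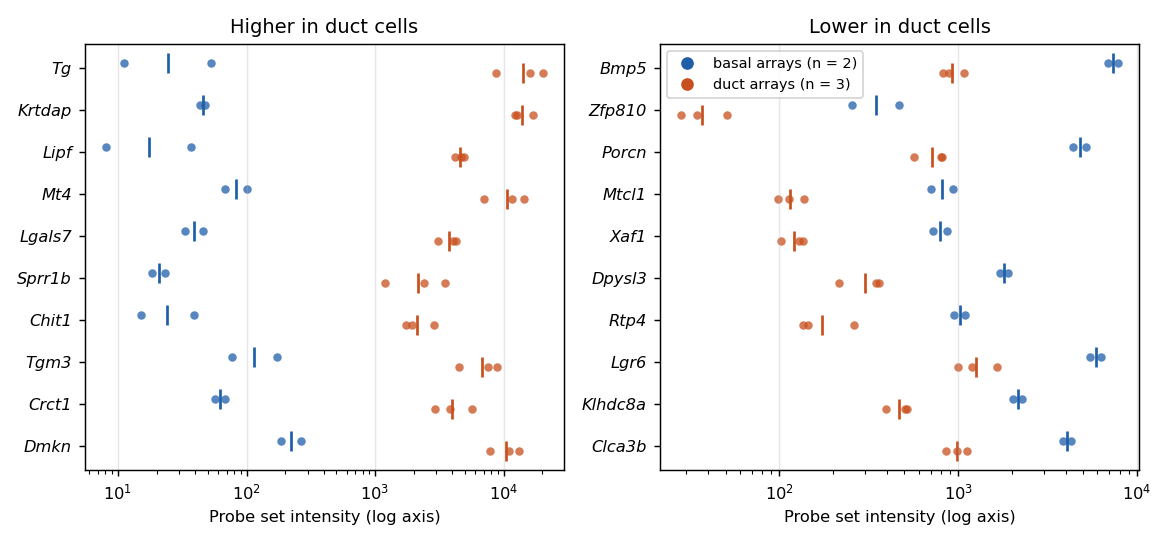
Intensity of single probe sets (log axis) of the 10 named genes with the largest increase (left) and the largest decrease (right) in duct cells. Each point is 1 array, basal (n = 2) in blue and duct (n = 3) in orange, and the vertical marks are geometric means; the groups do not overlap for any of the 20 genes.

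The 10 largest decreases were smaller. Bmp5 fell from 7319 ± 648 to 925 ± 129, a log2 fold change of -2.97 (SE 0.25, adjusted p = 0.0125). Porcn was at -2.71 (SE 0.28, adjusted p = 0.0225), from 4777 ± 525 to 725 ± 139. Zfp810, a zinc finger gene, was at -2.77, and its duct arrays were within the range of the Bacillus controls, which makes it at least 5.34-fold lower. Mtcl1, a microtubule crosslinking factor gene, was at -2.66, Dpysl3, a gene of the dihydropyrimidinase-like family, at -2.52, Klhdc8a at -2.16 and Clca3b at -2.02. Lgr6 fell from 5885 ± 590 to 1278 ± 334, at -2.22 (SE 0.30, adjusted p = 0.0427). Xaf1 and Rtp4, both interferon-stimulated, were at -2.56 and -2.45. With no filter on low values Bmp5 alone of these 10 genes was called, and the adjusted p of the other 9 ran from 0.0622 to 0.108. With the mean of its probe sets Mtcl1 was at -1.63, and its other tested probe set at -0.60. Without basal replicate 1 the most intense probe set was chosen anew from the arrays left, and the gene was at -0.60, the value of that other probe set. On the probe set of the main fit basal replicate 2 measured 702, against 97.6 to 136.7 on the duct arrays. Klhdc8a was not called with the mean of its probe sets (-1.24, adjusted p = 0.0532), which took in probe sets too dim for the main filter. With a pseudocount of 1 Lgr6 and Rtp4 were not called (adjusted p = 0.0546 and 0.0603).

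Itga6, the integrin chain used for the basal gate, measured 5250 ± 996 in basal and 6191 ± 169 in duct cells (log2 fold change 0.25, adjusted p = 0.628). Among 24 genes of airway basal cells, 2 rose and 0 fell over all genes, and 3 were higher and 1 was lower adjusted over the list alone; camera gave an adjusted p of 0.224 and fry one of 0.0378, higher. Krt14 rose from 1430 ± 146 to 19816 ± 2251 (log2 fold change 3.78, SE 0.24, adjusted p = 0.00595), and its 3 tested probe sets ran from 1.28 to 4.08. Krt17, a keratin of basal and stressed epithelia, rose from 2295 ± 38.5 to 8045 ± 379 (1.80, adjusted p = 0.0362). That call was lost without any one of the 5 arrays (adjusted p 0.0963 to 0.160 without a duct array) and with no filter on low values (0.0998). It was also lost with the mean of the gene's probe sets (0.98, adjusted p = 0.146), which took in probe sets too dim for the main filter. Krt5 measured 11976 ± 507 and 18134 ± 1532 (0.60, adjusted p = 0.256), and Trp63, a transcription factor of basal cells, 8964 ± 1310 and 7080 ± 152 (-0.33, adjusted p = 0.499). Krt15 measured 20227 ± 21.2 and 22325 ± 2229 (0.14, adjusted p = 0.790), a difference that turned to -0.05 with quantile normalization. Ngfr, a neurotrophin receptor gene of basal cells, measured 1806 ± 20.4 and 542 ± 186 (-1.76, adjusted p = 0.0786), and was at -1.02 with the mean of its probe sets. Small values moved with single arrays: Itga6 was at 0.44 and 0.06 without basal replicates 1 and 2, Trp63 at -0.18 without basal replicate 1 and Krt15 at 0.06 without duct replicate 3.

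Of 32 gene lists fixed beforehand and tested, camera called 6 higher and 2 lower in duct cells at a preset inter-gene correlation. With the correlation estimated from these arrays it called 0 lists, and 2 had an unadjusted p under 0.05; with fry, which tests whether a list's genes move one way on balance, 4 lists were higher and 2 lower.

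The squamous list moved most. Of its 25 tested members 14 rose and 0 fell, and adjusted over the list alone 21 were higher and 1 was lower, with a median log2 fold change of 2.80, or 2.70 with 5 members set at their lower bounds (camera adjusted p = 3.65e-23; adjusted p = 0.405 with an estimated correlation; fry adjusted p = 0.0191). Krtdap, Lgals7, Sprr1b and Tgm3 had the largest increases among its called members. The suprabasal keratins Krt13 and Krt4 rose from 1724 ± 416 to 22366 ± 3357 and from 6496 ± 1040 to 23479 ± 2330, and Krt6a, a keratin of activated and oral-type epithelia, rose from 1230 ± 24.3 to 18382 ± 956; these 3 were chosen after their values were seen. The same holds for the keratins and the envelope protein of cornified skin: Krt1, Krt10 and Lor had log2 fold changes of -0.57, -0.73 and -0.50, none past the test over all genes, and Krt10 was the member that was lower adjusted over the list alone. The number of its members called higher was 1, 0, 9, 7 and 1 without basal replicates 1 and 2 and duct replicates 1, 2 and 3, while the list's median stayed between 2.67 and 3.23. The thyroid list was higher in the same arrays, with a median of 1.19.

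The thyroid list had 6 tested members, all with a positive fold change and a median of 1.19 (camera adjusted p = 0.000297; adjusted p = 0.405 with an estimated correlation; fry adjusted p = 0.0425). Tg alone rose over all genes, and 2 members were higher adjusted over the list alone. Of the 3 duct arrays, each exceeded both basal arrays in Tg. With the lowest 60% of probe sets left out the list's median was 2.38.

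The cell cycle list, of genes of S phase and mitosis, was higher in duct cells with a median of 0.99, although 0 of its 27 members passed over all genes (camera adjusted p = 1.34e-09; adjusted p = 0.405 with an estimated correlation; fry adjusted p = 0.0425). Adjusted over the list alone, 14 members were higher and 0 lower, and 23 had a positive fold change. In the same arrays the thyroid list had a median of 1.19 and the leukocyte list, which did not pass camera, one of 0.57. Mki67, a marker of cycling cells, measured 3416 ± 115 in basal and 9340 ± 1132 in duct cells (1.44, adjusted p = 0.0679), and Pcna, the DNA polymerase clamp, 4390 ± 933 and 7193 ± 419 (0.72, adjusted p = 0.219).

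The interferon list was lower in duct cells, with a negative fold change in all 16 tested members and a median of -0.96 (camera adjusted p = 7.63e-06; adjusted p = 0.405 with an estimated correlation; fry adjusted p = 0.0378). Its members Xaf1 and Rtp4 fell over all genes, and 8 members were lower adjusted over the list alone. Xaf1 fell from 796.7 ± 102.1 to 121.6 ± 17.8 (adjusted p = 0.0202) and Rtp4 from 1018 ± 101 to 181 ± 70.7 (adjusted p = 0.0488). Both calls were lost without any one of the 5 arrays (adjusted p up to 0.128 and 0.1775 without a duct array). They were also lost with the mean of probe sets, at -1.13 (adjusted p = 0.175) and -1.59 (adjusted p = 0.0743). For Xaf1 that mean took in probe sets too dim for the main filter. The call of Rtp4 was lost with a pseudocount of 1 as well (adjusted p = 0.0603). The probe set of Ifi202b, an interferon-inducible gene outside the list chosen after its value was seen, went the other way. It rose from 1195 ± 293 to 7592 ± 1838 (2.64, adjusted p = 0.0330). That probe set is of the possibly cross-hybridising kind, so it may not measure this gene alone. The leukocyte list, which did not pass camera (adjusted p = 0.114), had a median of 0.57.

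**Figure D2:**
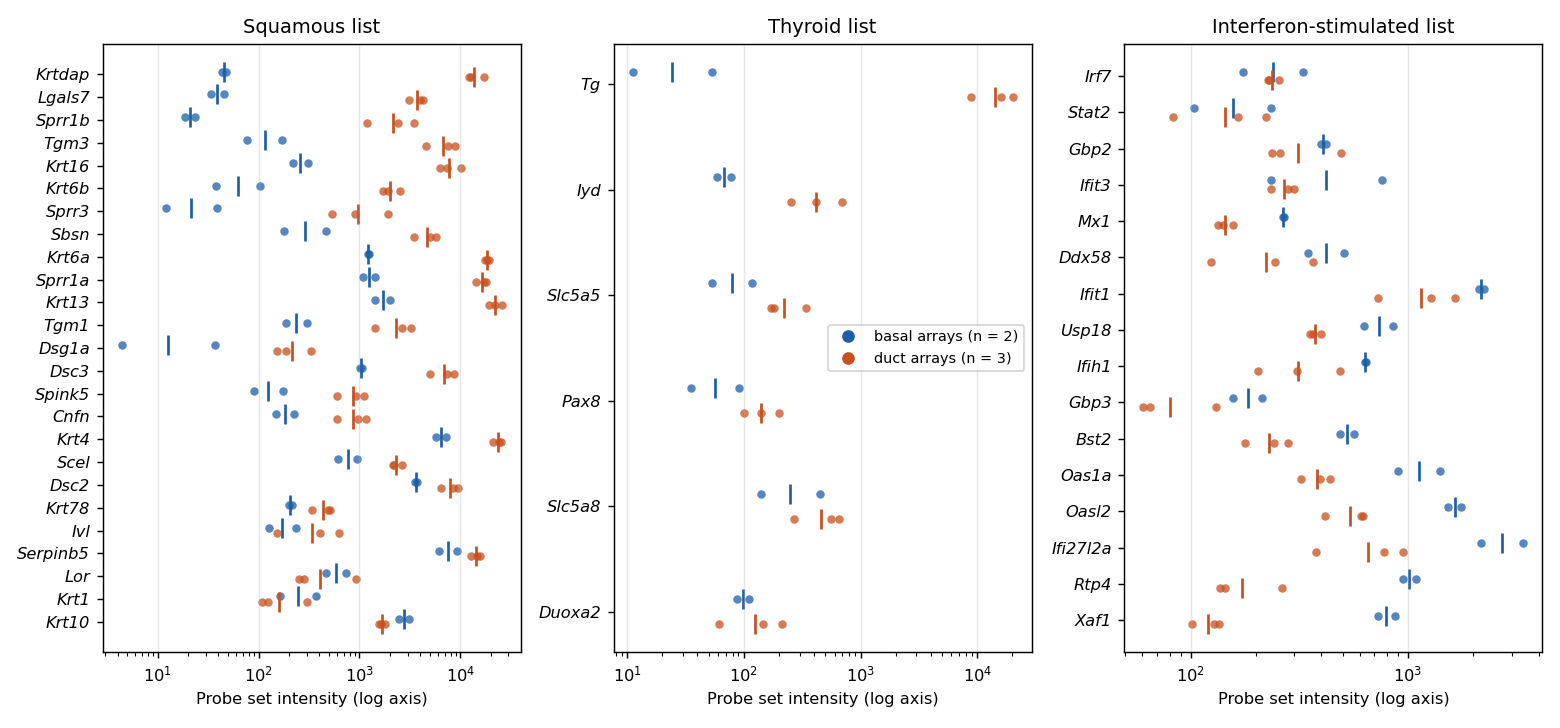
Intensity of the tested members of the squamous (25 genes), thyroid (6 genes) and interferon (16 genes) lists, 1 probe set per gene, on log axes. Each point is 1 array, basal (n = 2) in blue and duct (n = 3) in orange, vertical marks are geometric means, and genes are sorted by fold change; all 16 interferon list members have a lower mean log2 level in the duct arrays.

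Club cell genes, of the secretory cells of the airway surface, were lower in duct cells as a list: 0 of 15 passed over all genes, 6 were lower adjusted over the list alone, and the median was -0.55 (camera adjusted p = 0.00899; adjusted p = 0.552 with an estimated correlation; fry adjusted p = 0.0945). Without basal replicate 2 this list was no longer called (adjusted p = 0.182); its median was -0.83 without basal replicate 1 and -0.34 with median centring. The basal arrays lay far apart in some members: Scgb1a1 and Scgb3a1, secretoglobins chosen after their values were seen, measured 9934 and 7615 on basal replicate 1 and 32690 and 28609 on basal replicate 2. Scgb3a2, a secretoglobin, measured 32485 ± 287 and 22191 ± 1071 (-0.55, adjusted p = 0.272), and Cyp2f2, a cytochrome P450 of club cells, 30111 ± 742 and 25514 ± 614 (-0.24, adjusted p = 0.608).

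3 lists of metabolism and protein folding were higher in duct cells by small medians. The glycolysis and hypoxia list had 1 of 21 members higher and 0 lower over all genes, 4 higher adjusted over the list alone and a median of 0.47 (camera adjusted p = 0.00899; adjusted p = 0.516 with an estimated correlation). The called member was Egln3, an oxygen-sensing prolyl hydroxylase gene, at 101 ± 4.64 and 1315 ± 417 (3.47, SE 0.32, adjusted p = 0.0160). The list of endoplasmic reticulum folding genes had 0 of 24 members called, none adjusted over the list alone and a median of 0.16 (camera adjusted p = 0.00899; adjusted p = 0.405 with an estimated correlation). Its abundant members Calr and Atf4 had log2 fold changes of 0.11 and 0.15, neither past the test. The oxidative phosphorylation list had 0 of 27 members called, none adjusted over the list alone and a median of 0.21 (camera adjusted p = 0.0108; adjusted p = 0.573 with an estimated correlation). Its members Atp5a1 and Cox6c were at 0.08 and 0.21, neither past the test. With fry none of the 3 lists passed, at adjusted p of 0.0542, 0.0690 and 0.142. None of the 3 lists was called with quantile normalization, at camera adjusted p of 0.0839, 0.137 and 0.419. The median of the oxidative phosphorylation list was then 0.05; with median centring it was 0.41 (adjusted p = 0.0503), and that of the endoplasmic reticulum list 0.37. Without duct replicate 1 the endoplasmic reticulum and oxidative phosphorylation lists were not called (0.0587 and 0.111), nor was the latter without basal replicate 2 (0.0704).

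**Figure D3:**
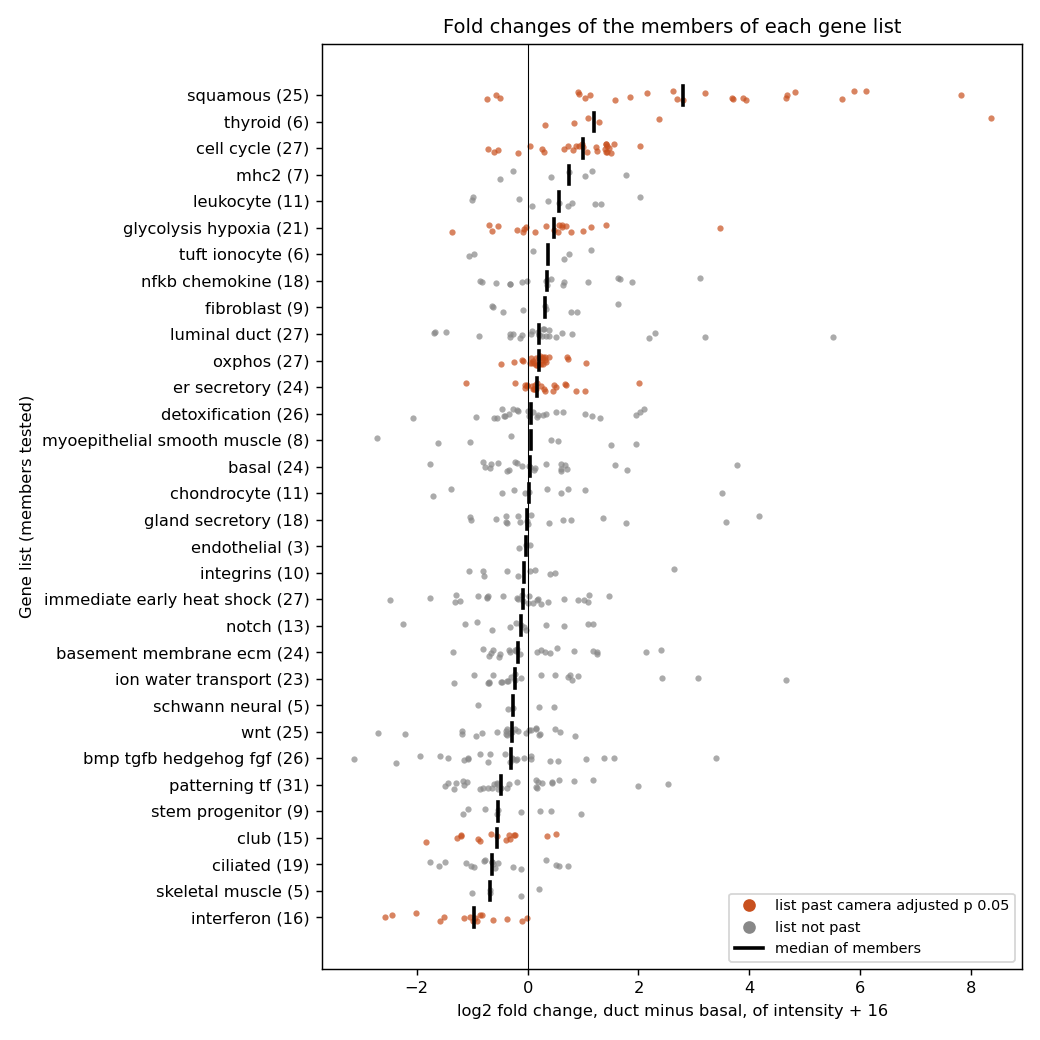
Log2 fold change, duct minus basal, of each tested member of the 32 tested lists (points) and each list's median (black bar), with the number of tested members in parentheses. Lists past a camera adjusted p of 0.05 are orange; the squamous list has the highest median, 2.80, and the interferon list the lowest, -0.96.

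Genes of gland secretion did not pass as a list. Of 18 tested members 0 were called over all genes and 2 were higher adjusted over the list alone, with camera at an adjusted p of 0.435, a median of -0.004 and a mean of 0.48. Bpifa1, a secreted airway protein, measured 42067 ± 808 and 41799 ± 5952 (adjusted p = 0.976), and Wfdc2, a secreted protease inhibitor family member, 23589 ± 55.6 and 21339 ± 616 (adjusted p = 0.766). Dmbt1 and Slpi, the 2 members adjusted over the list alone, were at 4.18 and 3.58 with adjusted p of 0.0976 and 0.0560, Slpi at least 6.70-fold. The basal arrays lay far apart in some members: on basal replicates 1 and 2 Muc5b, a gel-forming mucin gene, measured 8.81 and 1491, Bpifb1 845 and 9579, and Dmbt1 69.1 and 595. These 4 genes were chosen after their values were seen. Luminal and ductal genes had 2 of 27 members higher over all genes and 0 lower (camera adjusted p = 0.0507; adjusted over the list alone, 4 higher and 1 lower). The 2 were Cldn4, a tight junction claudin, from 804 ± 163 to 4016 ± 772 (2.29, adjusted p = 0.0387), and Krt23, a keratin, from 2311 ± 181 to 10649 ± 1103 (2.19, adjusted p = 0.0277), both named after their values were seen.

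Apart from the squamous, thyroid and club cell lists, lists of other cell types that the dissections could hold did not pass camera. For ciliated cells, 0 of 19 members were called (median -0.64, adjusted p = 0.138), with 2 lower adjusted over the list alone. For leukocytes, 0 of 11 members were called (median 0.57, camera adjusted p = 0.114), with 8 positive and 3 negative fold changes. Lyz2, a lysozyme gene of that list, measured 10850 ± 7745 and 16660 ± 3855. The lists of myoepithelial and smooth muscle, cartilage, fibroblast, endothelial, Schwann cell, skeletal muscle and tuft cell or ionocyte genes had 8, 11, 9, 3, 5, 5 and 6 tested members and 0 called. Their camera adjusted p were 0.494, 0.494, 0.553, 0.990, 0.990, 0.553 and 0.924. Adjusted over the list alone, 2 were higher and 1 lower for myoepithelial and smooth muscle, 1 higher and 1 lower for cartilage, and 0 for the other 5. Tpm2, a tropomyosin gene, measured 2173 ± 237 and 8654 ± 1999 (1.96, adjusted p = 0.0551). The red cell and neuroendocrine lists had 1 and 2 tested members, too few for a list test, and 0 called.

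Immediate early and heat shock genes are known to respond to tissue dissociation. All 27 tested members lay above the Bacillus controls on every array. The list did not pass (0 of 27 members called, median -0.08, camera adjusted p = 0.990), and adjusted over the list alone 3 were higher and 6 lower. Jun measured 30303 ± 4005 and 27984 ± 1572, and Dnajb1, a heat shock cochaperone, 34739 ± 870 and 32905 ± 1158.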

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

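The tests of explanations in this part, and Krt1, Krt10 and Lor, were chosen only after the results were seen. Groups of 2 and 3 arrays are too small for a test of outlying samples or of other splits of the samples. Outside the comparison of named genes, 4495 of the 27022 probe sets tested one by one carry no single gene name: 4 of them were higher and 1 was lower in duct cells at an adjusted p under 0.05 with limma. The 4 that were higher had log2 fold changes of 6.31, 6.05, 4.41 and 2.71, with adjusted p from 0.0131 to 0.0392, and the one that was lower was at -2.46 (adjusted p = 0.0487).

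The thyroid list was higher in the duct arrays with 1 of 6 tested members called, Tg, at 14987 in duct and 32.2 in basal cells (camera adjusted p = 0.000297; adjusted p = 0.405 with an estimated correlation). Scaling of the arrays is argued against by the fold change of Tg with quantile normalization, 8.31. Thyroid cells carried into the duct preparations remain a candidate source: without Tg, all 5 tested members had a positive fold change, with a median of 1.09, at percentile 99.8 of random lists matched on level, though these members were dim, Slc5a8 and Iyd, chosen after their values were seen, being the brightest at 494 and 457 in duct cells. Only 2 of the 6 tested members lay above the Bacillus controls on both basal arrays, and none is in another list; the sort would remove cells without the surface antigen it used. The leukocyte list, at percentile 99.89, stood as high among random lists, so a high percentile was not particular to thyroid genes. That list may itself differ between the preparations, so it is no null for this test. Transcription of Tg by duct cells themselves, the enzyme and the tracheal section stay open and untested.

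The squamous list was higher in the duct arrays, with 14 of 25 tested members called and a median of 2.80 (camera adjusted p = 3.65e-23; adjusted p = 0.405 with an estimated correlation). Scaling of the arrays is argued against by the list medians, the lower being 2.91 under quantile normalization and median centring. Krt1, Krt10 and Lor, the keratins and the envelope protein of cornified skin, had a median of -0.57. They were the 3 negative members of the list, picked after their values were seen, against 22 positive ones. The positive ones include Tgm3, an epidermal transglutaminase, at 5.68 and Sprr1b, of the cornified envelope, at 5.89. The 3 genes alone therefore do not settle whether cells of cornified skin-type epithelium were present. An admixture of squamous cells in differing share cannot be told apart from expression by the duct cells. A single source in differing share would shift all members alike and keep their ratios in a narrow range. The log2 ratios of duct replicate 1 to duct replicate 2 over 9 called members ran from 0.476 to 1.81. All 9 were thus higher in duct replicate 1. The SD of these ratios was 0.475, at percentile 85.4 of random lists matched on level. The 5 members near the top of the range were left out. The cell type, the tracheal section, the enzyme and the gate were not separated by the design and stay open.

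The interferon list was lower in the duct arrays, with 2 of 16 tested members called and a median of -0.96 (camera adjusted p = 7.63e-06; adjusted p = 0.405 with an estimated correlation). Leukocytes in the basal preparations are argued against by the leukocyte list, whose median was 0.57, opposite in direction. The lower dim end of duct replicate 1 is argued against by the list's median without that array, -0.98 (camera adjusted p = 1.67e-05). The cell type, the mice pooled, the tracheal section and the enzyme stay open and untested.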

How the results depend on the processing

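Counts of calls depended on the settings far more than directions did. Against 105 genes higher and 17 lower in duct cells, quantile normalization gave 143 and 28, median centring 281 and 57, a pseudocount of 1 gave 86 and 13 and of 64 gave 212 and 95, no filter 35 and 1, a filter at 60% gave 250 and 158, the mean of a gene's probe sets 160 and 65, exclusion of possibly cross-hybridising probe sets 112 and 19, an intensity trend with robust fit 565 and 377, array weights 129 and 40, and a 2-fold minimum 105 and 17. By probe set, 58 were higher and 5 lower. Leaving out single arrays gave 0 to 38 genes higher and 0 to 1 lower, with 2 residual degrees of freedom in place of 3; for the counts other than these, the cause was not tested. With the replicate number as a block and 1 residual degree of freedom, limma called 0 and 0 genes (650 and 958 at an unadjusted p under 0.05). In that fit camera called 9 lists higher and 2 lower. Same-numbered arrays had deviations from their group means correlated at -0.08 and -0.04. The deviations of 2 basal arrays are mirror images, so these values cannot tell whether the numbers pair samples. The samples were treated as unpaired because each was a separate pool of mice. Of 365 refits of the 23 called genes named by the rule, 240 kept the call and 125 lost it, and none turned in direction; of the called genes 118 of 122 were called again with quantile normalization and 35 of 122 with no filter. The one reversed value was Krt15, not called in any setting, at -0.045 with quantile normalization. Krt5 was called with the intensity trend (adjusted p = 0.00942), and Ngfr with it (0.00591), with a pseudocount of 64 (0.0467) and with a filter at 60% (0.0364). Lists higher in duct cells numbered 3 with quantile normalization, 0 with an estimated correlation and 4 to 8 without single arrays, against 6, and lists lower 0 with an estimated correlation and 1 to 3 without single arrays, against 2. The list tests were not run by probe set or with the 2-fold minimum, and the intensity trend with robust fit does not enter them; in the other settings the squamous, cell cycle, interferon and thyroid lists were called except by camera with an estimated correlation, and the endoplasmic reticulum list was also lost with the mean of probe sets (0.113) and the oxidative phosphorylation list with median centring (0.0503). Signal near the controls limits the folds of the 31 genes whose basal arrays lay in their range.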

Other observations

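Signalling lists not yet described held few or no calls. Of 25 tested Wnt genes 0 rose and 2 fell, Porcn and Lgr6, and the list did not pass camera (median -0.29, adjusted p = 0.224); both were also lower adjusted over the list alone. Of 26 genes of BMP, TGF-beta, hedgehog and FGF signalling 1 rose, Fst, the activin antagonist follistatin, from 32.3 ± 14.3 to 487.4 ± 108.4 (log2 fold change 3.39, at least 5.63-fold, adjusted p = 0.0194), named after its value was seen, and 0 fell; Bmp5, which fell, is not in this list, and adjusted over the list alone 4 were higher and 7 lower (camera adjusted p = 0.256). Of 13 Notch genes 0 were called (camera adjusted p = 0.990; 1 higher and 2 lower adjusted over the list alone), and the receptor Notch2 measured 5521 ± 301 and 6953 ± 428. Of 31 transcription factors of airway and regional patterning 0 were called (median -0.49, camera adjusted p = 0.289; 1 higher adjusted over the list alone). Sox2, a transcription factor of proximal airway epithelium, measured 5953 ± 291 and 2678 ± 513 (-1.16, adjusted p = 0.112). Of 9 genes used as stem or progenitor markers 0 were called (camera adjusted p = 0.494; fry adjusted p = 0.0425, lower; 1 higher and 2 lower adjusted over the list alone).

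Of 24 genes of basement membrane and matrix turnover 1 rose, Tnc, the tenascin-C gene, from 347 ± 68.8 to 1917 ± 360 (2.41, adjusted p = 0.0318), and 0 fell (camera adjusted p = 0.273; 3 higher and 1 lower adjusted over the list alone). Of 26 detoxification genes 1 rose, Gsta2, a glutathione transferase, from 509 ± 132 to 2212 ± 286 (2.10, adjusted p = 0.0415), and 0 fell (camera adjusted p = 0.140; 6 higher and 2 lower adjusted over the list alone). These 2 were chosen after their values were seen. Of 10 genes of other integrin subunits and an integrin-binding protein, 23 ion and water transport genes, 18 NF-kB target and chemokine genes and 7 MHC class II genes 0 were called, with camera adjusted p of 0.864, 0.507, 0.0987 and 0.114. Adjusted over the list alone, 1, 3, 2 and 0 of them were higher and 0 lower. The median, the mean and the camera or fry direction differed in sign for the gland secretion, ion and water transport, matrix, Notch, myoepithelial, endothelial, Schwann cell, integrin and tuft cell or ionocyte lists.

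Sex-linked genes differed between the pools. Kdm5d, a Y-linked gene, measured 326.6 and 587.1 on the basal arrays, 601.1 and 647.9 on duct replicates 1 and 2, and 5.83 on duct replicate 3. Xist, the X-inactivation transcript, measured 15590 and 8243 on the basal arrays and 10408, 10418 and 15274 on the duct arrays. Uty, also Y-linked and chosen after its values were seen, measured 46.7 on duct replicate 3. Eif2s3y, Kdm5d and Uty thus lay under the brightest Bacillus control of that array, 61.9, and above the controls on every other array. The pool of duct replicate 3 showed no Y-linked signal above background in these genes.

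Ideas on signalling were tested on genes outside the fixed lists, written down before those genes' values were looked at. Higher NRF2 activity in duct cells, as a source of the detoxification genes that were higher, was not settled. The 16 other targets of this oxidative stress regulator had a median log2 fold change of 0.42, with 13 of 16 positive. This stood at percentile 99.7 of random lists matched on level and passed the mark fixed beforehand, which lay at 0.242. The unrelated leukocyte list, compared only afterwards, stood at percentile 99.89 in the same test. A high percentile was therefore not particular to NRF2 targets. The leukocyte list may itself differ between the preparations, so it is no null for this test. Of the 16 targets Ptgr1 rose (2.34, adjusted p = 0.0415), and Hmox1 was at 3.06 (adjusted p = 0.0551). The enzymes used to free the cells differed between groups, so handling could act on the same genes and was not tested. Lower FGF and ERK signalling, prompted by Spry1 and Spry2 at -1.44 and -1.93, was not settled. The 10 other feedback genes had a median of -0.25, at percentile 14.0 of random lists, with 7 of 10 negative. At an unadjusted limma p under 0.05, 2 of them were lower and 2 higher. Dusp6 was at -1.43 (adjusted p = 0.0786) and Dusp5 at 1.08 (adjusted p = 0.134). The genes named in this part were chosen after their values were seen.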
